A study of Mus musculus with 3 samples.

How the data were processed

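The series used ATAC-seq, which reads accessible chromatin through the insertion of sequencing adapters by Tn5 transposase, on mouse hepatocytes from animals given an adeno-associated virus. The 3 libraries analysed here carry the label EV, the control virus that expresses Cre recombinase from the hepatocyte-active TBG promoter. The labels put harvest 4 days after injection. Hepatocytes were freed by liberase digestion and enriched on Percoll, and nuclei were taken from sorted cells, per the labels' protocols, which do not name the marker of the sort. Libraries of the Sox4 virus were not analysed here. The labels do not say that the 3 libraries came from separate animals, so the spread between them may be partly technical.

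Bowtie2, Picard, deepTools and MACS2 and the genome build mm10 are named per the submitters' processing notes, without the settings used for alignment or duplicate removal. Peaks were called with MACS version 2.2.7.1 on each library separately and without a control library, per the file headers. The headers record single read ends shifted by 100 bp and extended to 200 bp so that each pileup is centred on the transposase cut, all duplicates in the input kept, summits called within peaks, and a q cutoff of 0.05. The signal column is the pileup of extended tags at each summit, deposited by the authors without scaling for depth. The −log10 p and −log10 q columns were deposited by the authors and set each summit against the background of its own library. The fold enrichment column, a ratio of the pileup to that background, was also deposited by the authors. The background is the higher of the genome-wide level and a regional level taken over 10000 bp, so a summit in a broadly accessible region, or beside a very tall signal, gets a lower fold than its pileup alone would give. Because no input or control library entered the calling, copy number and repeated sequence are not corrected for. The peaks' scores and folds are the authors' own, and were used only to describe, rank or filter peaks within a list.

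The headers give 96066404, 116147036 and 117450440 tags for replicates 1, 2 and 3. A peak list holds no counts for regions without a peak, so absence of a peak means only that the region did not pass the authors' threshold in that library, and no interval for a region's level can be given. Lines that shared chromosome, start and end, which are several summits of 1 peak, were counted as 1 peak. Peaks of different libraries were called overlapping when they shared 1 bp or more, and overlapping peaks were merged into regions. Regions with a peak of all 3 libraries are called reproducible. Overlap was compared with 100 random placements of the peaks on their own chromosomes.

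Gene positions came from the RefSeq table of assembly GRCm38.p6, whose coordinates are those of mm10. It gives the start and end of each gene without strand, exons or sequence. The planned promoter window around transcription start sites was therefore replaced by a window of 1000 bp on either side of either gene end, so the end of transcription is included. Summits were classed as near a gene end, elsewhere in a gene body, or intergenic, and exons were not separated from introns. The planned motif counts at summits and the list tests at matched CpG content need a genome sequence and were not run. The background was 21631 protein-coding genes on chromosomes 1 to 19 and X.

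There were 22 gene lists, fixed before the data were examined, with 390 entries. Of these, 387 entries matched the table, and they made up 379 distinct genes. Ahsp, Mx1 and Mx2 were not matched, and Tf was matched as Trf. For each list, the number of genes with a gene-end peak in all 3 libraries was compared with that of all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 22 lists. Odds ratios were computed after adding 0.5 to each cell. The median number of reproducible regions outside gene ends, from 50 kb before a gene to 50 kb after it, was compared with 10000 random lists of equal size matched on local gene density, two-sided, with the same adjustment. Genes are not independent replicates, and these tests describe the 3 libraries. On simulated data of 21631 genes with 10 changed lists of 20 genes among 22 lists, the gene-end test recovered 97.4% of lists set to 98% or 20% open and called 0.917% of unchanged lists. The test of distal regions recovered 83.5% of lists with doubled counts and called 1.42% of unchanged lists, over 100 simulations each. Its simulation counted all reproducible regions, those at gene ends included, and used fewer random lists than the test itself. Simulated lists were genes drawn at random, without the neighbouring genes that some real lists hold. These rates are therefore not exactly those of the tests applied.

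The genes named were chosen by a rule fixed before the data were examined. It always takes a fixed set of genes that includes Alb, Hnf4a, Cebpa, Foxa2, Sox4, Sox9, Epcam, Krt19, Krt7 and Spp1. From each list it takes up to 3 members with a gene-end peak in all 3 libraries and the highest mean percentile of fold within the lists of peaks, and up to 2 members with no gene-end peak, in alphabetical order. It adds the 10 gene ends and the 10 distal regions with the highest mean percentile. Some genes the rule takes are not reported here. The fold given for a gene is that of its gene-end peak with the highest percentile in each library, so it can belong to different regions, as it does for 10 of the 82 genes the rule took that had a gene-end peak in all 3 libraries (Cx3cr1, Esrra, Flt1, Fosl1, Gpc3, Notch1, Rnf43, Saa3, Sox9 and Spp1). Genes named outside the rule are said to have been chosen after their values were seen.

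After the Sox4 locus had been seen, each library in turn was compared with both others. A peak was counted as found only in 1 library when its −log10 q was 10 or more there and no peak overlapped it in either other list. A region was counted as missing from 1 library when both others held a peak with −log10 q of 10 or more and the library held none. Genes of a list whose windows of 50 kb overlapped were joined into 1 locus, and the number of such peaks or regions in the loci of each list was compared with 10000 draws of 1 random gene window per locus. Each window held about as many peaks of −log10 q of 10 or more in that library as the locus did or, for missing regions, as many regions present in both others (within 10%, or the 50 nearest windows). These tests were two-sided, with Benjamini-Hochberg adjustment over the 132 tests of 3 libraries, 22 lists and both kinds. Gene ends open in 1 library only, or closed in 1 library only, were compared between each list and the other genes by Fisher's exact test among genes closed, or open, in both other libraries, with the same adjustment. Alternatives covered a −log10 q minimum of 10, the 50000 peaks with the highest −log10 q per library, each library left out, a reciprocal overlap of 50%, other windows of 500 and 2500 bp at gene ends and of 20 and 100 kb around genes, and a gene-end peak in any library. Those added after seeing the data were random lists matched on gene length as well, genes with overlapping windows counted once, an equal number of peaks per library, and a peak anywhere in a gene. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.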

Results

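Chromatin accessibility was profiled by ATAC-seq in hepatocytes, the main parenchymal cells of the liver, from wild-type mice given the control virus EV. The series asks how forced expression of Sox4, a transcription factor of the SRY-related family, alters the accessible chromatin of adult hepatocytes. Its Sox4 libraries were not analysed here, so the accessible chromatin of 1 group of 3 libraries is described and no comparison between treatments was made. The peak lists held 108997, 119230 and 110455 peaks for replicates 1, 2 and 3 (mean 112894 ± 5535 SD, n = 3), called from 96066404, 116147036 and 117450440 tags. The median peak length was 498 ± 8.08 bp and the peaks covered 70.9 ± 3.48 Mb (SD, n = 3). Coordinates are those of mm10.

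The Sox4 gene itself was examined first in every library, because the series' other virus carries Sox4. The gene lies at chromosome 13, 28948919 to 28953699. In EV replicate 1 its peak ran from 28952003 to 28953938, with a highest pileup of 128, rank 55819 of 108997 peaks by pileup. In EV replicate 3 it ran from 28951916 to 28953918, with a highest pileup of 134, rank 60777 of 110455. In the library labelled EV replicate 2 a peak of 1460 bp from 28951662 to 28953121, inside the gene, reached a pileup of 2544, rank 9 of 119230. That is 20.4 times the median pileup of its own list, against 0.962 and 0.854 times in replicates 1 and 3. The ratio to the highest other library was 19.0, while the ratio of their total tags was 0.989. The sequence between 28953121 and the ends of the other 2 intervals held no called peak in that library. So tall a signal raises the regional background beside it. Summits such as those of replicates 1 and 3 there, with pileups of 83 to 134, may therefore not have been callable, and this absence is not a further difference. By its height, the Sox4 signal of the library labelled EV replicate 2 stood apart from both other EV libraries. Values without this library are given below for the overlaps, the gene ends, the distal regions and some of the gene lists.

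**Figure D1:**
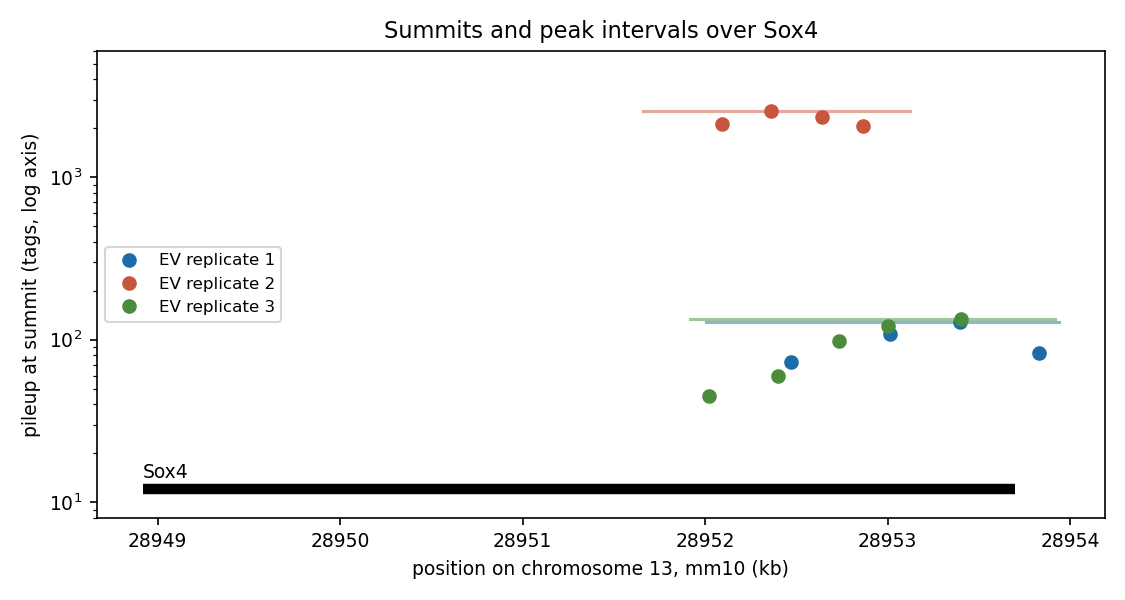
Summits (points) and peak intervals (lines, drawn at the height of the tallest summit) over Sox4 in the 3 EV libraries, with position on chromosome 13 in kb against the authors' pileup in tags on a log axis that is not scaled for depth; the black bar is the gene. The 4 summits of the library labelled EV replicate 2 lie between 2077 and 2544 and those of the other 2 libraries between 45 and 134.

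Most accessible regions recurred between the libraries. Of each library's peaks, 80.5%, 73.9% and 79.6% overlapped a peak in both others (78.0 ± 3.57%, SD, n = 3), against means of 4.56%, 4.91% and 4.50% over 100 random placements. Merging gave 139455 regions, of which 85711 (61.5%) were reproducible. Replicates 1 and 3 shared 84.2% of their merged regions, whereas the pairs holding the library labelled EV replicate 2 shared 66.1% and 66.7%. Leaving out any library raises the overlap, since fewer lists must then agree. Without the library labelled EV replicate 2 it was 91.5 ± 0.658% (SD, n = 2), with 98853 regions in both remaining libraries, against 80.5 ± 4.33% and 90297 without replicate 1 and 80.1 ± 4.86% and 89164 without replicate 3. Overlap followed peak strength. In the top 10% of each list by −log10 q it was 99.99%, 99.8% and 100%, and in the lowest 10% it was 34.8%, 29.9% and 32.2%. No pair of libraries was near identical.

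**Figure D2:**
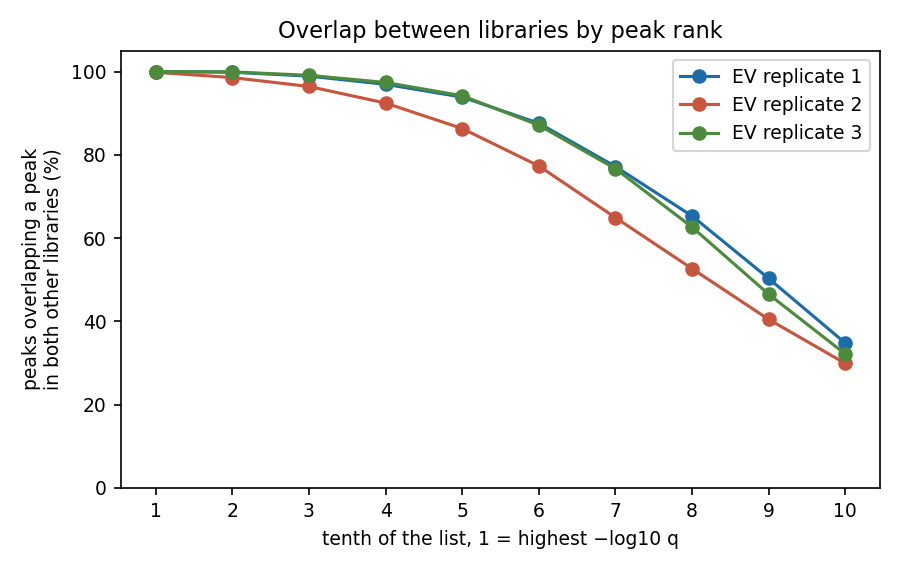
Percentage of peaks that overlap a peak in both other libraries (vertical axis) by steps of 10% of each list ranked by the authors' −log10 q (horizontal axis, 1 is the highest), 1 line per library. All 3 lines start above 99.8% and end between 29.9% and 34.8%, and the line of the library labelled EV replicate 2 is the lowest in every step.

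When each library was set against both others, the library labelled EV replicate 2 held 13204 peaks found only there at a −log10 q of 10 or more, against 1424 in replicate 1 and 1727 in replicate 3. It lacked 7790 regions present in both others, against 1256 and 633. The difference was not limited to weak peaks. Among the peaks in the upper 50% of its list, 2155 (3.61%) were found only there, against 2 in each of the others. Of the regions in the upper 50% of both other lists, 784 (1.52%) had no peak in it, against 1 in replicate 1 and 0 in replicate 3. These are values of single libraries without a replicate check.

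**Figure D3:**
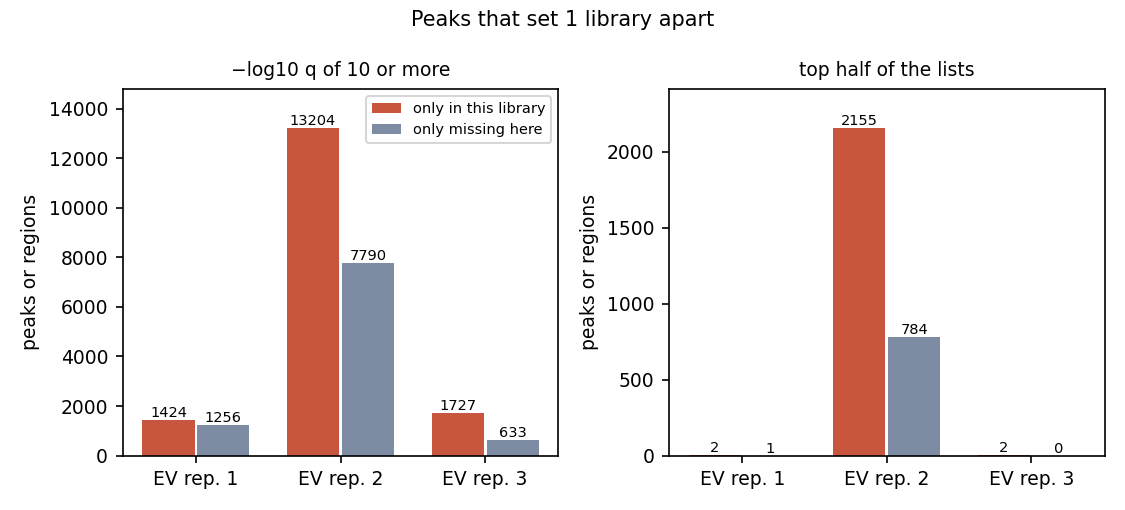
Numbers of peaks found in 1 library only and of regions missing from 1 library only (vertical axes), for peaks with −log10 q of 10 or more (left) and for the upper 50% of the lists (right), each bar a single count without error. The library labelled EV replicate 2 has the highest bars in both panels, with 13204 and 7790 on the left and 2155 and 784 on the right.

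Accessible sites gathered at the ends of genes. Within 1000 bp of an end of a protein-coding gene lay 13.9 ± 0.272% of summits, against 3.01% of the genome, a 4.63 ± 0.0902-fold excess (SD, n = 3). A further 49.8 ± 0.690% lay elsewhere in gene bodies, which make up 37.9% of the genome, and 36.3 ± 0.912% were intergenic against 59.1% of the genome. In total 13925 of 21631 protein-coding genes (64.4%) had a gene-end peak in all 3 libraries, 2999 (13.9%) had one at both ends, and 6363 (29.4%) had none in any library. The remaining reproducible regions, 70012 in number, lay away from gene ends. Without the library labelled EV replicate 2 these numbers were 14054, 3516, 7165 and 82201, against 14093, 3140, 6442 and 74199 without replicate 1 and 14055, 3157, 6398 and 73150 without replicate 3.

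Genes of hepatocyte function and identity were accessible almost throughout. All 31 genes of the hepatocyte function list, which holds secreted plasma proteins, urea cycle and gluconeogenic enzymes and bile acid genes, had a gene-end peak in all 3 libraries, against 64.3% of other genes (odds ratio 34.9, Fisher's exact adjusted p = 3.36e-05). Among hepatocyte transcription factors the number was 21 of 22 (odds ratio 7.94, Fisher's exact adjusted p = 0.00392). The 1 member not open in all was Creb3l3, named after its values were seen, which had no gene-end peak in the library labelled EV replicate 2; without that library the odds ratio was 24.3. Alb, the gene of serum albumin (chromosome 5, 90460870 to 90476602), had fold enrichments of 6.71, 5.51 and 5.37 in replicates 1, 2 and 3. By mean percentile of fold the function list was led by F9, coagulation factor IX (20.4, 18.2 and 17.9), Abcb11, the bile salt export pump (12.5, 9.26 and 13.5), and Fga, the fibrinogen alpha chain (10.2, 9.77 and 9.04). The regulators were led, by the same measure, by Nr1h3, which encodes the oxysterol receptor LXR alpha (16.9, 17.3 and 17.4), Esrra (8.73, 10.2 and 8.82) and Nr1h4, the bile acid receptor gene (9.95, 8.45 and 9.12). Hnf4a, a central regulator of hepatocyte identity (chromosome 2, 163506811 to 163572907), had folds of 6.05, 14.2 and 7.098, Cebpa 3.22, 5.15 and 3.72, and Foxa2 4.03, 3.84 and 3.97. The Hnf4a folds are those of a region at the lower coordinate of the gene (163506438 to 163507141 in replicate 1). Peaks farther inside the gene do not enter them. Gene-end peaks of the function list had a median fold percentile of 45.2 ± 6.45 within their lists of peaks, against 76.5 ± 2.92 over all genes and 73.0 ± 2.28 for the 26 housekeeping genes (SD, n = 3), so their openness was not a matter of the highest folds. The fold is relative to the region around each summit, so a low percentile of fold need not mean a low pileup. The gene-end peak of Alb, 1 member, reached pileups of 704, 920 and 976 in replicates 1, 2 and 3. The median pileups of their lists of peaks were 133, 125 and 157.

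**Figure D4:**
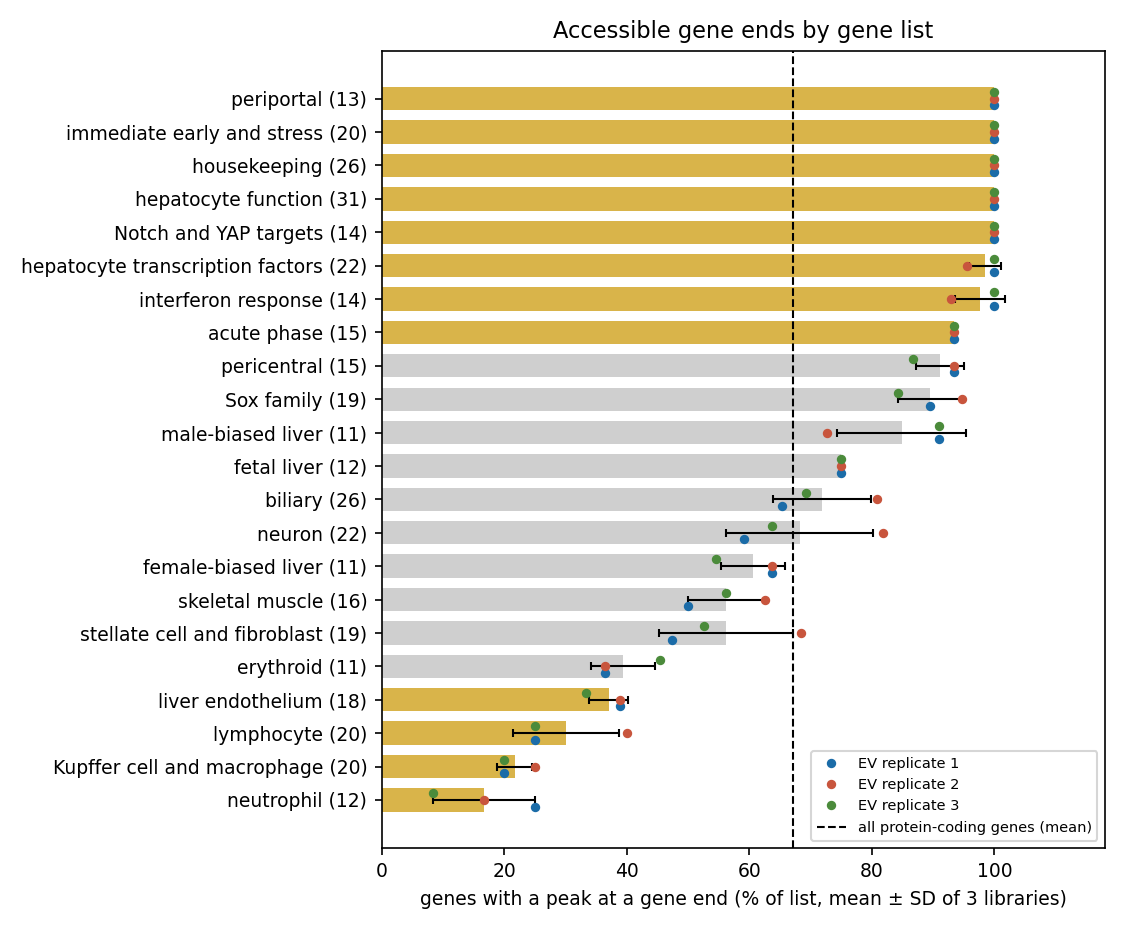
Percentage of each gene list with a peak within 1000 bp of a gene end (horizontal axis), with the list size in brackets; bars are the mean and whiskers the SD of the 3 libraries, points the single libraries, and the dashed line the mean of all protein-coding genes. Bars in yellow passed an adjusted p of 0.05 in Fisher's exact test on peaks present in all 3 libraries, 8 lists above and 4 below the other genes.

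The zonal, stress and housekeeping groups were also open. A gene-end peak in all 3 libraries was present at 26 of 26 housekeeping genes (adjusted p = 0.000151), 20 of 20 immediate early and stress genes (0.000934), 14 of 14 Notch and YAP targets (0.00831) and 13 of 13 periportal genes (0.0136), all by Fisher's exact test. With 50000 peaks per library the Notch and YAP targets (exact adjusted p = 0.136) and periportal genes (0.0770) lost the call, and so did both with a peak anywhere in the gene (0.0682 and 0.0889). Examples were Emc7 (fold 18.9, 20.1 and 19.5), Nr4a1 (13.3, 13.6 and 15.6), Notch2, a Notch receptor (10.8, 10.7 and 11.8), and Hal, the histidine-degrading enzyme of periportal hepatocytes (8.57, 9.94 and 8.94). Interferon response genes had 13 of 14 and acute phase genes 14 of 15 open, both at an adjusted p of 0.0491, with Ifit1 (18.2, 13.4 and 17.9) and Saa3 (20.1, 18.4 and 14.9) among the first by percentile of fold. Both calls were lost without replicate 1 (exact adjusted p = 0.0819 and 0.0532), with 50000 peaks per library (0.136 and 0.0979) and with a peak anywhere in the gene (0.314 and 0.214). The acute phase call was also lost at a −log10 q of 10 or more (exact adjusted p = 0.0974), with windows of 500 bp (0.0830) and with an end peak in any library (0.132). Without the library labelled EV replicate 2 the interferon odds ratio rose from 4.98 to 15.7. This rests on 1 gene, Isg15, named after its values were seen, which had no gene-end peak in that library only. With all 14 genes then open, the size of the odds ratio depends on the 0.5 added to each cell. Saa1 had no gene-end peak in any library. Pericentral genes had 13 of 15 open, including Rhbg (13.3, 15.9 and 15.4) and Rnf43 (11.6, 13.4 and 11.8) but not Axin2, and did not pass the test (exact adjusted p = 0.142; 0.0445 without replicate 3).

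Marker genes of the blood and vascular cells of the liver were mostly closed. A gene-end peak in all 3 libraries was found at 4 of 20 Kupffer cell and macrophage genes (odds ratio 0.151, adjusted p = 0.000466), 1 of 12 neutrophil genes (0.0721, adjusted p = 0.000519), 5 of 20 lymphocyte genes (0.196, adjusted p = 0.00196) and 5 of 18 endothelial genes (0.225, adjusted p = 0.00574), by Fisher's exact test. Each of these 4 lists lay below all protein-coding genes in all 3 libraries. Adgre1 and C1qb of macrophages, Cd2 of lymphocytes, Camp and Csf3r of neutrophils, and Cdh5 and Clec4g of endothelium had none. The open members included Spi1, a regulator of myeloid cells (fold 19.5, 17.7 and 20.6), Cx3cr1 (12.5, 12.3 and 12.7), Fcer1g, Tie1 (18.1, 15.02 and 17.4), Flt1, Robo4, Tcf7, Cd4 and Elane. A gene-end window can hold an element of a neighbouring gene, or the end instead of the start of transcription. The endothelial call was lost with a window of 2500 bp (11 of 18 open, exact adjusted p = 0.589) and with an end peak in any library (0.127), and with a peak anywhere in the gene the odds ratio turned to 3.97 (17 of 18, exact adjusted p = 0.0980), while the lymphocyte call was also lost there (0.05002). The library labelled EV replicate 2 had 8 open lymphocyte genes against 5 in each other library.

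Lists of stellate cells and other lineages did not pass the test at the settings used here, but several did at others. Stellate cell and fibroblast genes had 8 of 19 open in all 3 libraries (Fisher's exact adjusted p = 0.0918), with Ecm1 (16.7, 16.3 and 17.5), Col1a1 (16.1, 13.8 and 16.1) and Nes open and Col3a1 and Dcn closed. By library the numbers were 9, 13 and 10. Erythroid genes had 4 of 11 (0.0988), with Klf1 (14.9, 14.3 and 15.8) and Ermap open and Epb42 and Gata1 closed. Skeletal muscle genes had 7 of 16 (0.149), with Actn3, Cacna1s and Mylpf open and Myf5 and Myh1 closed, and neuronal genes 13 of 22 (0.724), with Snap25 (19.4, 26.0 and 22.9), Tubb3 and Rbfox3 open and Neurod1 closed. In the library labelled EV replicate 2, 18 neuronal genes were open, against 13 and 14. With 50000 peaks per library the stellate (odds ratio 0.243, exact adjusted p = 0.00990), neuronal (0.203, p = 0.00203) and muscle (0.301, p = 0.0414) lists passed below the other genes, and with windows of 500 bp the stellate (0.189, p = 0.00169), erythroid (0.172, p = 0.0186) and muscle (0.312, p = 0.0329) lists did. With an end peak in any library the stellate (1.10) and neuronal (1.71) odds ratios turned above 1, as did the neuronal one with 2500 bp (1.31) and with a peak anywhere in the gene (1.89). Fetal liver genes had 9 of 12 open (odds ratio above 1, exact adjusted p = 0.644), but with 50000 peaks per library 2 of 12, which reversed the odds ratio to 0.199 and passed (exact adjusted p = 0.0324), and with 500 bp the odds ratio was 0.653. Gpc3 (13.6, 11.7 and 14.9), Lin28b (8.57, 11.3 and 8.45) and Dlk1 (4.43, 8.80 and 4.28) were open, and Igf2 and Igf2bp3 were not.

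Several biliary loci were accessible in these hepatocytes. Of 26 genes of cholangiocytes, the cells that line bile ducts, 17 had a gene-end peak in all 3 libraries (odds ratio 1.02 to other genes, Fisher's exact adjusted p = 1). The odds ratio depended on the settings and fell to 0.454 with 50000 peaks per library (exact adjusted p = 0.0770) and to 0.484 with windows of 500 bp (0.0910), and was 1.63 with an end peak in any library (0.376). By library the numbers were 17, 21 and 18. Pkhd1, the gene of fibrocystin (chromosome 1, 20057779 to 20618082), had folds of 29.4, 28.0 and 28.4 and was among the first 10 gene ends of all genes by mean percentile of fold. That peak lay at the lower coordinate of the gene (20058217 to 20058702 in replicate 1). Strand was not at hand, so it cannot be read as the promoter of Pkhd1. Muc1 (18.6, 17.5 and 19.4), Elf3 (13.7, 15.8 and 14.6) and Epcam, an epithelial adhesion molecule (chromosome 17, 87635979 to 87651127; 13.95, 12.8 and 12.6), followed. Sox9 (6.06, 7.06 and 6.001) and Spp1, the gene of osteopontin (5.87, 3.16 and 2.89), were open in all 3. The folds of Spp1 belong to a different peak in each library, and the region of the first, 104436105 to 104437279 in replicate 1, had 3.85 and 6.25 in replicates 2 and 3 but lay outside the window there. Those of Sox9 also come from different peaks. Krt19, a keratin of bile duct cells (chromosome 11, 100140810 to 100145926), had no gene-end peak in any library, as had Cftr and Ehf. Krt7 had a weak one, fold 2.68, in the library labelled EV replicate 2 and none in the others.

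The Sox family was open at 16 of 19 genes (odds ratio 2.61, Fisher's exact adjusted p = 0.135; 17 of 19 without replicate 3, adjusted p = 0.0445; 18 of 19 with an end peak in any library, 0.0417). With 50000 peaks per library the odds ratio turned to 0.502 (7 of 19, exact adjusted p = 0.192). By mean percentile of fold the first were Sox30 (10.5, 14.6 and 12.3), Sox6 (11.3, 11.4 and 11.4) and Sox13 (10.5, 9.75 and 10.2), and Sox14 had no gene-end peak in any library. Sox9 (chromosome 11, 112782210 to 112787757) had 8 reproducible regions away from gene ends within 50 kb, Sox4 had 6 and Krt19 had 1. Sox4, which is also on the biliary list, was counted as open in all 3 libraries. Its gene-end peak with the highest percentile in the library labelled EV replicate 2, fold 8.69, was the tall interval described above.

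Genes with sex-biased expression in liver showed no list-wide difference. Of the female-biased genes 6 of 11 were open in all 3 libraries (odds ratio 0.654, Fisher's exact adjusted p = 0.644; 1.01 with an end peak in any library and 2.38 with a peak anywhere in the gene), with Hao2 (15.1, 13.01 and 11.3), Abcd2 and Acot3 open and Cyp2b13 and Cyp3a41a closed, and of the male-biased genes 8 of 11 (adjusted p = 0.792), with Mup20 (16.4, 16.5 and 15.1), C6 and Cyp7b1 open and Ugt2b38 closed. By library, 10, 8 and 10 male-biased genes were open, and without the library labelled EV replicate 2 the odds ratio was 3.78 instead of 1.34 (Fisher's exact adjusted p = 0.143). The Y chromosome carried 41, 45 and 44 peaks and the X chromosome 2425, 2385 and 2488. Kdm5d, Eif2s3y, Uty and Ddx3y, widely expressed genes of the Y chromosome, had a gene-end peak in all 3 libraries.

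Hepatocyte loci were rich in accessible regions away from gene ends. Genes of hepatocyte transcription factors had a median of 13 such reproducible regions within 50 kb and those of hepatocyte function 10, against a median of 5 in random lists matched on gene density (permutation adjusted p = 0.00440 for both, from 10000 random lists, the smallest they could give for hepatocyte transcription factors). Hnf4a had 24, Alb 18, Nr1h4 18, Cebpa 14, Foxa2 14 and Fga 14. Without the library labelled EV replicate 2 the medians were 17 and 14, against 14.5 and 11 without replicate 1 and 13 and 11 without replicate 3, and periportal genes, with a median of 9 in all 3 libraries (permutation adjusted p = 0.195), reached 13 without the library labelled EV replicate 2 and passed the test (permutation adjusted p = 0.0381). Endothelial genes had a median of 9.5 and immediate early genes 8.5, both at an adjusted p of 0.0715, and passed with a window of 100 kb (permutation adjusted p = 0.0418 for both). No other list passed with 50 kb, all 3 libraries and random lists matched on gene density. With random lists matched on gene length as well, immediate early genes passed (permutation adjusted p = 0.00147) and endothelial genes did not (0.180). Male-biased genes had a median of 10 (permutation adjusted p = 0.168) and pericentral genes 9 (0.195). Notch and YAP targets, housekeeping, acute phase and female-biased genes had 7, interferon genes 6.5 and biliary genes 6. Fetal liver, lymphocyte, neutrophil and erythroid genes had 5, the Sox family, Kupffer cell, stellate cell and muscle genes 4, and neuronal genes 3.

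Of the 10 gene ends with the highest mean percentile of fold, only that of Pkhd1 belonged to a gene of the lists fixed beforehand. The others were at Wdr31 (28.4, 27.0 and 30.1), Ankrd45 (28.8, 27.5 and 28.7), Trim34a (27.3, 28.1 and 29.0), Adgrv1, Trim21, Dnajc24, Shcbp1, Rfc3 and Csrp1. The first distal region by the same measure lay within Cmss1 (chromosome 16, 57391362 to 57391773; 43.0, 40.8 and 42.2), followed by regions 170614 bp from Samd9l (chromosome 6, 3201329 to 3201643; 42.4, 40.6 and 43.5) and 262647 bp from Mc2r (chromosome 18, 68691967 to 68692398; 41.2, 39.5 and 40.9). A region at chromosome 1, 24612560 to 24612943, 24638 bp from Col19a1, differed most among these 10, with folds of 32.5, 27.3 and 47.7. No control library entered the calling, so copy number or repeated sequence may contribute to such extreme folds. They cannot be taken as a measure of accessibility alone.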

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

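The data outside the comparisons were peaks on contigs not placed on a chromosome. Their numbers were 92 in EV replicate 1, 87 in the library labelled EV replicate 2 and 80 in EV replicate 3, and no control library stood beside them. With 3 libraries in 1 group, no test for a single outlying sample and no difference between groups applied.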

How the results depend on the processing

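The choices added after seeing the data were matching on gene length, counting genes with overlapping windows once, an equal number of peaks per library, and a peak anywhere in a gene; the others were fixed before the data were examined. No paired analysis was possible because all 3 libraries belong to 1 group. Motif counts and list tests at matched CpG content, with their alternatives, were not run for lack of a genome sequence. Hepatocyte function, hepatocyte transcription factors, immediate early genes and housekeeping genes stayed above, and Kupffer cell and neutrophil genes below, the other genes at gene ends under every alternative run, and both hepatocyte lists stayed past the threshold for distal regions. The cause of the changes below was not tested, except where fewer peaks, fewer libraries or a wider window set a value. Values for lists are odds ratios at gene ends unless distal medians are named.

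At a −log10 q of 10 or more, 15.03% of summits lay near gene ends and 62.3% of genes had an end peak. The biliary odds ratio turned to 0.950 and the acute phase one, 3.27, lost its call. With 50000 peaks per library, 39046 reproducible regions remained, 22.6% of summits lay near gene ends, 54.4% of genes and 15 Sox and biliary genes had an end peak, and means of 826 and 10.3 peaks lay on chromosomes X and Y. There the biliary (0.454) and Sox family (0.502) odds ratios turned below 1, and the fetal liver one (0.199) did so and passed the threshold. Stellate (0.243), neuronal (0.203) and muscle (0.301) genes passed the threshold, and periportal (3.85), interferon (2.75), acute phase (2.99) and Notch and YAP (2.75) genes no longer did.

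Leaving out each library in turn gave overlaps of 80.1% to 91.5%. Odds ratios ranged from 0.993 to 1.16 for biliary, 2.52 to 3.78 for Sox family, 2.89 to 5.22 for pericentral, 4.82 to 15.7 for interferon and 5.18 to 5.22 for acute phase genes, and the periportal distal median from 10 to 13. A reciprocal overlap of 50% gave 67.0% overlap.

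With 2500 bp at gene ends, 21.4% of summits and 70.9% of genes were counted, the biliary odds ratio was 0.895 and the neuronal one 1.31, both reversed, and the endothelial one, 0.630, lost its call. With 500 bp, 10.7% of summits and 60.5% of genes were counted, biliary (0.484) and fetal liver (0.653) odds ratios reversed, stellate (0.189), erythroid (0.172) and muscle (0.312) genes passed, and acute phase genes (3.53) did not. With an end peak in any library, 70.6% of genes were open, the Sox family (5.15) passed, endothelial (0.416) and acute phase (4.03) genes did not, and stellate (1.10), neuronal (1.71) and female-biased (1.01) odds ratios turned above 1. With a peak anywhere in the gene 74.6% of genes were open, endothelial (3.97), neuronal (1.89) and female-biased (2.38) odds ratios turned above 1, and lymphocyte (0.339), periportal (9.18), interferon (3.06), acute phase (3.29) and Notch and YAP (9.86) genes lost their calls.

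Distal medians in a window of 100 kb were 10, 11 and 11 for the Sox family, neutrophil and muscle genes, which turned from below to above random lists, and 15.5 and 15 for endothelial and immediate early genes, which passed the threshold. In a window of 20 kb the interferon median of 2 turned below random lists. With random lists matched on gene length too, Sox family (4) and neutrophil (5) medians turned above random lists and immediate early genes (8.5) passed. Counting genes with overlapping windows once moved no list across the threshold.

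Taking an equal number of peaks per library left the overlap at 78.0%. The end-peak state of the named genes held for 95 of 110 with 500 bp, 100 with 2500 bp, 108 at the higher −log10 q and 101 with 50000 peaks per library. Over all alternatives the adjusted exact p ranged from 0.0445 to 0.215 for pericentral, 0.0417 to 0.671 for Sox family, 0.0770 to 1 for biliary, 0.0324 to 1 for fetal liver, 0.00854 to 0.314 for interferon, 0.0235 to 0.214 for acute phase and 0.000154 to 0.589 for endothelial genes. At distal regions the permutation adjusted p ranged from 0.0381 to 0.2002 for periportal, 0.0418 to 0.749 for endothelial and 0.00147 to 0.588 for immediate early genes. Depth limits what the absence of a weak peak can show.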

Other observations

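All tests in this part were chosen after the Sox4 locus had been seen, and each describes single libraries. The cut-offs for weighing explanations were also set after the data were examined. Peaks found only in the library labelled EV replicate 2 were set against random gene windows that held as many of its peaks. By that measure 1 of the 132 tests passed. Around the 18 loci of stellate cell and fibroblast genes lay 34 such peaks of 141, against 15.1 in random windows (ratio 2.25, permutation adjusted p = 0.0264, the smallest these 10000 draws could give here), and without the 8 around Reln the 26 others stood against 13.5 (unadjusted permutation p = 0.00620). Of the other lists, fetal liver genes held 31 against 15.9 (permutation adjusted p = 0.259), the Sox family 40 against 27.4 (0.713), 15 of them around Sox5, biliary genes 44 against 30.3 (0.617), endothelial genes 36 against 24.8 (0.713), Notch and YAP targets 31 against 21.8 (0.973), muscle genes 19 against 13.8 (1), female-biased genes 19 against 13.9 (1), lymphocyte genes 25 against 18.6 (1), neuronal genes 25 against 19.98 (1), immediate early and stress genes 43 against 34.4 (1) and Kupffer cell genes 17 against 15.1 (1). The 10 lists below random windows were housekeeping genes with 18 against 33.9 (permutation adjusted p = 0.259), hepatocyte function genes with 34 against 50.7 (0.600) and, all at an adjusted p of 1, hepatocyte transcription factors (32 against 42.8), acute phase (7 against 13.2), interferon (11 against 17.3), erythroid (7 against 10.2), male-biased (11 against 14.4), neutrophil (8 against 9.94), pericentral (20 against 21.9) and periportal genes (22 against 22.7).

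Regions missing only from the library labelled EV replicate 2 numbered 45 around hepatocyte function genes, against 41.3 in random windows with as many regions (ratio 1.09, permutation adjusted p = 1), 44 around hepatocyte transcription factors against 36.8 (ratio 1.20, adjusted p = 1) and 23 around male-biased genes against 12.8 (ratio 1.79, adjusted p = 0.259), by the same permutation test. Fewer than in random windows were missing around stellate cell genes (2 against 6.68, ratio 0.299) and biliary genes (11 against 18.99, ratio 0.579), both at a permutation adjusted p of 0.713. None of the 22 lists passed for these regions, nor for replicates 1 and 3 in either direction. Gene-end peaks found only in the library labelled EV replicate 2 numbered 802, against 79 in replicate 1 and 35 in replicate 3. Among genes closed in both other libraries they were at 4 of 8 neuronal genes (Syt1, Neurog1, Nefl and Gap43; exact adjusted p = 0.497), 3 of 8 stellate cell genes (Rgs5, Col1a2 and Hand2; 0.790), 3 of 8 biliary genes, Krt7 and Aqp1 among them (0.790), 3 of 15 lymphocyte genes (Bcl11b, Pax5 and Cd3e; 1), 2 of 11 endothelial genes (Mmrn2 and Erg; 1), 2 of 7 muscle genes (Mb and Pvalb; 1) and 1 gene each of the Kupffer cell (C1qa), Sox family (Sox1) and female-biased (Cyp2b9) lists (1 for each), against 11.1% to 11.2% of other genes. Gene ends open in both other libraries and not in this one numbered 129, no more than the 168 for replicate 1 and 130 for replicate 3. The listed genes among the 129 were Hsd3b5 and Cyp4a12a of the male-biased list, Creb3l3, Oit3, Myog and Isg15. For the male-biased list this was 2 of 10, against 0.904% of other genes (Fisher's exact adjusted p = 0.473). No list passed this gene-end test for any library. Genes in this part were named after their values were seen.

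These values depend on the matching. A count per gene against random lists matched on gene density and length only, which counts regions shared by neighbouring genes more than once and does not allow for loci rich in peaks, passed 13 of 132 tests. For the library labelled EV replicate 2 they were immediate early genes (ratio 3.27), Notch and YAP targets (2.43) and the Sox family (2.42) for peaks found only there, and male-biased (3.13), acute phase (2.91), periportal (2.38) and stellate cell genes (0.157), hepatocyte transcription factors (2.91) and hepatocyte function genes (2.51) for missing regions, with permutation adjusted p from 0.00660 to 0.0447. The others were hepatocyte function genes for peaks found only in replicate 1 or replicate 3, hepatocyte transcription factors for replicate 1 and acute phase genes for replicate 3. The stellate cell list did not pass there for peaks found only in the library labelled EV replicate 2 (ratio 1.77, permutation adjusted p = 0.198), and hepatocyte function genes (1.36), hepatocyte transcription factors (1.42) and acute phase genes (1.93) lay above random lists instead of below.

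The tall Sox4 peak of the library labelled EV replicate 2 was weighed first. Depth cannot account for it, since the ratio of total tags to the library with the next highest pileup was 0.989 against a pileup ratio of 19.0, and a gain of the surrounding chromosome is argued against by 69 regions within 1 Mb, whose pileup divided by total tags had a median ratio of 0.904 to the mean of the other libraries and an upper quartile of 1.44. The Sox4 region had a ratio of 16.4 to the higher of the other libraries, the highest of all 85711 reproducible regions, and among the 1210 at listed genes the next was 10.5. It may come from DNA of a Sox4-carrying virus, which would align to the gene, but the height of the peak prompted this hypothesis and does not test it independently. Opening of the native gene was not excluded either. Only 1 other gene-end peak of that library was as tall. A peak at chromosome 1, 88276569 to 88277879, was taller there, with a pileup of 3490. In replicate 1 a peak from 88276750 to 88277879 reached 2815. Whether this is the gene-end peak counted, and how tall that one was in the other libraries, was not examined. The count therefore cannot decide the question. The shape of the tall Sox4 interval is a feature apart from its height. That interval spanned 1460 bp inside the gene, with 4 summits of 2077 to 2544 tags. In both other libraries the peak ran past the upper gene coordinate, 28953699, to 28953938 and 28953918. The raised background beside the tall signal may hide that stretch. The interval was not compared with the coding sequence that a virus would carry, because exon positions and sequence were not at hand. These values therefore do not separate vector from chromosome.

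The regions missing from this library were weighed second. It lacked 6.202 times as many as the library with the fewest tags, which argues against sequencing depth as the whole cause. Of the regions in the upper 50% of both other lists, 784 (1.52%) were missing, against 1 and 0 in the other libraries. That argues against a small carry-over of another library, which removes no strong regions, as the cause of this loss. It also argues against light dilution by added immune or endothelial cells, which would remove weak regions first. How many strong regions a heavier dilution would remove was not measured, so that stays undecided.

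The peaks found only in this library were weighed last. They were 7.65 times as many as in the library with the most tags, which argues against depth as the whole cause. Immune or endothelial cells stay open for these peaks, since the highest ratio to random windows among the Kupffer cell, endothelial, lymphocyte and neutrophil lists was 1.45 for endothelium (permutation adjusted p = 0.713), and so do stellate cells, since 37.5% of the stellate genes closed in both other libraries had a gene-end peak there while Col3a1 and Dcn had none, although Percoll enrichment and a sort, whose marker the labels do not name, preceded the isolation of nuclei and may have removed such cells. With 50000 peaks per library the higher of the pairs holding this library shared 68.5% of regions and replicates 1 and 3 shared 88.8%, and this gap of 20.4 points together with the Sox4 signal prompted the hypothesis that the library came from a Sox4-injected animal, which cannot be tested because what a Sox4 library would give was not analysed here. A difference between animals, cell preparation or sequencing may give the gap as well. Apart from cells of other types, no biological explanation of the peaks found only in this library was tested, because only 1 group was analysed here.

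The tallest pileups in all 3 libraries lay at chromosome 17 from about 39843086 to 39846626, with 8602, 14684 and 11274 tags in replicates 1, 2 and 3 and folds of only 2.73, 2.54 and 2.79. The region at chromosome 1, 24612560 to 24612943, reached a pileup of 5821 in replicate 3. Copy number and repeated sequence were not corrected for and may contribute to these pileups, so they cannot be taken as a measure of accessibility alone. No peaks were listed on the mitochondrial genome.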
